A study of Homo sapiens with 6 samples.

How the data were processed

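RNA was sequenced from 6 libraries of T98G glioblastoma cells collected 48 h after hairpin delivery, 3 with the control hairpin sh-NC and 3 with the hairpin against CHASERR. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, Trimmomatic, HISAT2, HTSeq and Cufflinks were used, with no order, version or setting given. The same notes name the mouse build mm10, while 19356 of the 20030 gene rows carry a human HGNC identifier and the labels give human cells, so the build behind the values is not known and no coordinates are given here. The deposited table holds 14400 genes with curated and 5630 with predicted mRNA accessions. Strand handling is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

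Per the file headers, the authors deposited FPKM per gene and library, and these values were the input of every test. FPKM sums differed between libraries, from 325411 in sh-NC replicate 1 to 371982 in sh-CHASERR replicate 3. The deposited signal columns hold the authors' mean normalized counts per group. Such means do not show the depth of the libraries, which is not known. Their low values rose in steps of 1 read for genes seen in 1 library, which gave size factors of 0.92 to 1.1, with 65.8% to 78.7% of such genes at whole multiples within a tolerance of 0.001. The deposited fold is the quotient of the authors' group means (largest relative difference 2.5e-08), and the deposited p-value and its adjusted form come from the authors' comparison. The authors' log2 column was not used because 1015 of its cells held no number. No gene counts per library were used here. Of the gene names, 12 had been turned into dates and 0 rows belonged to mitochondrially encoded genes.

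A count test had been planned. Because the per-library values were FPKM, the fallback written with that plan was used: limma (version 3.58.1, in R 4.3.3) with an intensity trend on log2(FPKM + 1), two-sided, on genes with an FPKM of at least 0.5 in at least 3 libraries, with Benjamini-Hochberg adjustment over the 11059 genes tested. Every adjusted p of a gene is from this limma fit unless credited to the authors' deposited table. A log2 fold change on this scale understates the change of low genes. The precision of FPKM depends on read counts per gene and library, which were not used here. No 2 libraries were copies of each other, with the same value at no more than 0.02% of genes in any pair. The genes named in the text followed a rule fixed before the data were examined. It took CHASERR, CHD2 and TRIM14, then the 6 higher and 6 lower genes with the largest change among those with an adjusted p under 0.05, a mean FPKM of at least 1 and no overlap between groups. It added up to 4 called members with the lowest p of each of the 8 gene lists with the lowest p, and up to 2 of any other list described. Other names are said to be chosen after their values were seen.

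In all, 50 gene lists were fixed before the data were examined, and the 44 with at least 5 tested genes were compared with all other genes by camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera called 18 lists, 8 higher and 10 lower. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05. The test fry asks whether a list's genes move on balance one way and called 9 lists; its mixed form, for change in either direction, called 40. Neither form compares a list with other genes. Enrichment of Gene Ontology terms and pathways with 10 to 300 tested genes was tested with Fisher's exact test, one-sided, separately for higher and lower genes, among the tested genes for which the deposited table carries such an annotation. Transcript length and GC content came from GENCODE release 29, with a length for 95.6% of genes. The scripts were tested on simulated data for the comparison of sh-CHASERR with sh-NC over 11059 genes. The limma step recovered 23.0% of genes changed by 0.5 in log2, 74.0% of those changed by 1 and 99.1% of those changed by 2, with 3.3% of calls false, and camera called 0 of 100 unchanged lists and all 5 shifted ones. The simulated genes varied independently, whereas camera estimated a correlation of 0.81 within the interferon list of the real data. These rates therefore do not show how often calls are false where genes vary together. Over 5 simulations, 335, 335 and 330 genes were changed by 0.5, 1 and 2, and 54295 were left unchanged. In the real data a larger share was called, 2271 of 11059 genes. Recovery depends on that share, so the simulated percentages do not give the recovery in the real data. Alternatives were another pseudocount, no filter, a stricter filter, 4 other scalings, a correction for length and GC content, limma's treat, a block on the replicate number, other list tests, and leaving out each library in turn.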

Results

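Gene expression was measured by RNA sequencing in T98G cells, an established human glioblastoma line, 48 h after delivery of a short hairpin RNA. Of the 6 libraries, 3 came from cells given a control hairpin (sh-NC) and 3 from cells given a hairpin against CHASERR (sh-CHASERR). CHASERR is a long noncoding RNA made from a gene just upstream of CHD2, a chromatin remodelling ATPase. The labels name the libraries of a group as replicates but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The authors' deposited table gives FPKM (fragments scaled by transcript length and by the mapped fragments of the library) per library for 20030 genes. The depth of the libraries is not known, and the size factors recovered from the steps of low values in the authors' mean normalized counts ran from 0.92 to 1.1. Between 10501 and 11146 genes reached an FPKM of 0.5 in a library, and the correlation of log2(FPKM + 1) across genes was 0.985 to 0.994 within groups and 0.967 to 0.980 between them. Genes are not independent replicates in such a correlation.

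The comparison of sh-CHASERR with sh-NC asked which genes change when CHASERR is targeted in glioma cells. CHD2 fell in sh-CHASERR, from 13.1 ± 1.56 FPKM (SD, n = 3) to 4.0 ± 1.41 FPKM (SD, n = 3). TRIM14, a tripartite motif protein of innate immune signalling named before the data were examined, fell from 4.19 ± 1.37 FPKM to 1.85 ± 0.234 FPKM (SD, n = 3 each). The log2 fold change on the log2(FPKM + 1) scale was -1.53 (SE 0.195, limma adjusted p = 0.000781) for CHD2 and -0.84 (SE 0.183, limma adjusted p = 0.0091) for TRIM14, with no overlap between the libraries of the groups for either gene. The FPKM of CHD2 was 12.5, 11.9 and 14.9 in sh-NC replicates 1, 2 and 3 and 3.95, 5.44 and 2.61 in sh-CHASERR replicates 1, 2 and 3. The level of CHASERR itself was not analysed here, so the targeted RNA gave no check of the labels. In the reference annotation CHASERR and CHD2 lie on chromosome 15 on the same strand, with 487 bp between the end of CHASERR and the start of CHD2, and an annotated protein-coding gene, AC013394.1, overlaps both. Reads from such a shared transcript could not be told apart from those of CHD2 in the deposited values. TRIM14 was no longer called without a filter on low values or against a minimum fold of 1.2. TRIM14 also belongs to the list of interferon-stimulated genes described below.

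**Figure D1:**
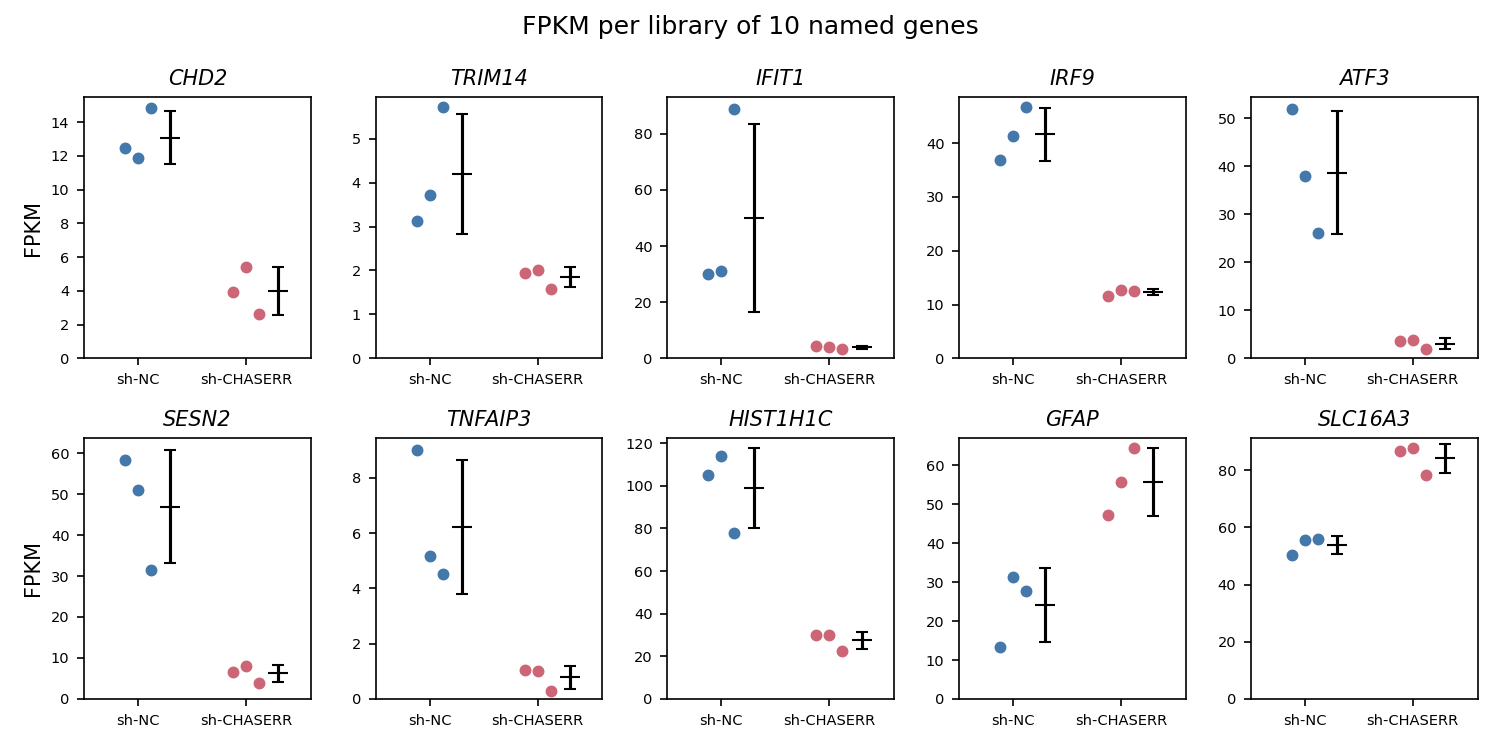
FPKM of 10 named genes in each library (linear axes from 0), with sh-NC in blue and sh-CHASERR in red, and the black mark and whiskers giving the mean and SD of 3 libraries. The sh-CHASERR libraries lie below every sh-NC library for CHD2, TRIM14, IFIT1, IRF9, ATF3, SESN2, TNFAIP3 and HIST1H1C and above for GFAP and SLC16A3; CHD2 fell from 13.1 to 4.0 FPKM on average.

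By the rule fixed before the data were examined (a mean of at least 1 FPKM and groups that did not overlap), the largest falls were of C11orf96, ATF3, IFIT1, IFIT3, OAS1 and MX1, and the largest rises of CA9, GFAP, C1QL1, CRYAB, PSD4 and FOXS1. C11orf96 fell from 20.5 ± 9.21 to 0.980 ± 0.547 FPKM (log2 fold change -3.39), and ATF3, a stress-induced transcription factor, fell from 38.7 ± 12.9 to 3.10 ± 1.08 FPKM (log2 fold change -3.26). CA9, a hypoxia-inducible carbonic anhydrase, rose from 1.59 ± 0.879 to 7.10 ± 4.80 FPKM (log2 fold change 1.52, limma adjusted p = 0.0166). GFAP, the intermediate filament protein of astrocytes, rose from 24.1 ± 9.43 to 55.8 ± 8.65 FPKM (log2 fold change 1.25), and CRYAB, a small heat shock protein, rose from 13.1 ± 0.894 to 31.0 ± 6.97 FPKM (log2 fold change 1.17). The rises of C1QL1, a secreted C1q-like protein, and PSD4, an exchange factor for ARF6, had log2 fold changes of 1.23 and 1.15. FOXS1, a forkhead transcription factor, rose from 0.395 ± 0.142 to 2.05 ± 0.704 FPKM, with a log2 fold change of 1.11 that went to 2.10 with a pseudocount of 0.1. With no filter on low values, CA9, GFAP and PSD4 lost their calls, and the authors' deposited table gives CA9 an adjusted p of 0.138. Of 11059 genes tested, 2271 changed at an adjusted p under 0.05 by limma, 790 of them higher and 1481 lower in sh-CHASERR. Changes of at least 2-fold numbered 259, of which 14 were higher and 245 lower, and 596 with a pseudocount of 0.1. The higher genes numbered 426 with the replicate block and 1309 with the length and GC correction. The groups did not overlap for 38.6% of genes, against 10% by chance. The counts fell to 1058 changed genes (261 higher, 797 lower) without sh-NC replicate 1 and to 1217 (368 higher, 849 lower) without sh-CHASERR replicate 1, the lower genes fell to 946 without sh-CHASERR replicate 3, and CA9 lost its call without sh-NC replicate 1 (log2 fold change 1.21). The share of calls that were higher was 34.8% as deposited, but 16.9% with equal totals, 45.3% with median-ratio scaling, 43.6% with upper-quartile scaling and 54.6% with quantile normalization; equal totals moved the median log2 fold change of all genes from -0.073 to -0.175.

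Interferon-stimulated genes fell together. Of 42 tested genes of this list, 36 fell and none rose by limma, with a median log2 fold change of -1.57. The authors' deposited table calls 23 of them lower and 0 higher. IFIT1, which binds viral RNA, fell from 50.0 ± 33.5 to 3.99 ± 0.498 FPKM (log2 fold change -3.17, limma adjusted p = 0.000192). The authors' deposited table gives IFIT1 an adjusted p of 0.02. IRF9, the DNA-binding part of the transcription factor complex downstream of type I interferon, fell from 41.6 ± 4.89 to 12.3 ± 0.558 FPKM (log2 fold change -1.68, limma adjusted p = 3.86e-05). OASL and IRF1 fell with log2 fold changes of -2.35 and -2.05, IFIT3 with -2.99, OAS1 with -2.95 and MX1 with -2.89. The list was called lower by camera (adjusted p = 1.61e-21; adjusted p = 0.51 with an estimated correlation), and 39 members were lower when adjusted over the list alone. Relative to the sh-NC mean, the list median was -0.45, -0.23 and 0.71 in sh-NC replicates 1, 2 and 3 and -1.62, -1.37 and -1.62 in sh-CHASERR replicates 1, 2 and 3. Without sh-NC replicate 3, 33 members were called lower, and with the filter at 5 FPKM, which tests fewer genes, 22. Genes of antigen presentation fell in part, with 7 lower and 1 higher of 16 tested (8 lower and 1 higher adjusted over the list alone), among them the peptide transporter TAP1 (log2 fold change -1.40) and the class I molecule HLA-B (log2 fold change -1.09). This list had a median of -0.37 (-0.24 without sh-NC replicate 3) and a camera adjusted p = 0.00373 (adjusted p = 0.576 with an estimated correlation), and its higher gene, the chaperone CALR, named after its value was seen, lost its call without sh-NC replicate 1, without sh-CHASERR replicate 1 or without sh-CHASERR replicate 2, with 0 then called higher. IFIT, OAS and HLA genes belong to families of similar sequence, and values of single members are uncertain where the authors' counting split shared reads.

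Many inflammatory and immediate early genes were also lower. Of 20 tested genes of the NF-kB and cytokine list, 12 fell and none rose (14 lower adjusted over the list alone), with a median log2 fold change of -0.81. RELB and NFKB2, subunits of the noncanonical NF-kB pathway, fell with log2 fold changes of -1.72 and -1.60, TNFAIP3, an inhibitor of NF-kB signalling, fell from 6.23 ± 2.43 to 0.785 ± 0.419 FPKM (log2 fold change -2.00, limma adjusted p = 0.000515), and the chemokine CXCL8 fell with -1.95. Of 25 immediate early and AP-1 genes, 18 fell and 2 rose (21 lower and 2 higher adjusted over the list alone), with a median of -0.71. KLF4, EGR1 and DUSP5 fell with log2 fold changes of -1.94 (-2.97 with a pseudocount of 0.1), -1.41 and -2.06 besides ATF3. Camera called both lists lower (adjusted p = 2.86e-07 and 2.38e-08; adjusted p = 0.51 for each with an estimated correlation). Of 22 YAP/TEAD targets, 10 fell and 1 rose (13 lower and 1 higher adjusted over the list alone), with a median of -0.48 and a camera adjusted p = 0.000159 (adjusted p = 0.51 with an estimated correlation). CTGF, a matricellular growth factor, fell from 331 ± 6.78 to 190 ± 22.6 FPKM (log2 fold change -0.81), and GADD45B, NUAK2 and AJUBA fell with -1.86, -0.94 and -1.10. The few higher members, named after their values were seen, did not hold in every set of libraries. Those of the immediate early list, JUND and IER3, went from 2 to 0 without sh-NC replicate 1 and to 1 without sh-NC replicate 3 or any 1 sh-CHASERR library, and that of the YAP/TEAD list, FOXF2, from 1 to 0 without sh-NC replicate 1 or 2 or sh-CHASERR replicate 1 or 3.

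Some stress response genes fell as well. Of 35 genes of the unfolded protein response and ATF4 list, 17 fell and 3 rose (20 lower and 4 higher adjusted over the list alone), with a median log2 fold change of -0.52 and a camera adjusted p = 0.000723 (adjusted p = 0.646 with an estimated correlation). SESN2, a stress-inducible regulator of amino acid sensing, fell from 47.0 ± 13.9 to 6.21 ± 2.09 FPKM (log2 fold change -2.73, limma adjusted p = 0.000101), and the pseudokinase TRIB3 fell from 56.3 ± 16.9 to 14.2 ± 1.81 FPKM (log2 fold change -1.87). The 3 genes that rose, named here after their values were seen, were SDF2L1, PDIA4 and HYOU1, which help fold proteins in the endoplasmic reticulum. Without sh-NC replicate 1 or 2 or sh-CHASERR replicate 1 or 2 there was 1 higher member, and without sh-CHASERR replicate 3 there were 5. With no filter on low values, 10 members were called lower. Of 24 p53 target genes, 8 fell and none rose (8 lower and 1 higher adjusted over the list alone), with a median of -0.30 and a camera adjusted p = 0.0111 (adjusted p = 0.51 with an estimated correlation). GADD45A, a growth arrest gene, fell from 187 ± 89.1 to 23.9 ± 3.42 FPKM (log2 fold change -2.82). SESN2 stands in this list too, and GADD45A and SESN2 are also known targets of ATF4.

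Some genes of RNA processing and ribosome assembly were lower. Of 29 MYC targets and ribosome biogenesis genes, 9 fell and none rose (13 lower adjusted over the list alone), with a median log2 fold change of -0.34 and a camera adjusted p = 0.0014 (adjusted p = 0.51 with an estimated correlation). WDR43 and NOP56, which act in the maturation of ribosomal RNA, fell with log2 fold changes of -0.84 and -0.67. Of 33 splicing factors, 10 fell and none rose (13 lower adjusted over the list alone), with a median of -0.29 (-0.17 without sh-NC replicate 3 and -0.13 with the length and GC correction) and a camera adjusted p = 0.0016 (adjusted p = 0.646 with an estimated correlation). CLK1, a kinase of SR proteins, fell from 10.1 ± 2.37 to 3.20 ± 0.387 FPKM (log2 fold change -1.38), and TRA2B fell with -0.88. Of 10 replication-dependent histone genes, 3 fell and none rose (3 lower adjusted over the list alone), with a median of -0.33 (-0.50 without sh-CHASERR replicate 2 and -0.19 without sh-CHASERR replicate 3) and a camera adjusted p = 0.0102 (adjusted p = 0.646 with an estimated correlation). HIST1H1C, a linker histone, fell from 99.0 ± 18.8 to 27.5 ± 4.12 FPKM (log2 fold change -1.80), HIST1H4H fell with -1.62 (not called with no filter on low values), and HIST1H2AC, named after its value was seen, fell too. The median of the histone list relative to the sh-NC mean was -0.40, -0.11 and -0.78 in sh-CHASERR replicates 1, 2 and 3. Single histone genes are uncertain because family members share sequence. Without sh-NC replicate 1, 5 ribosome biogenesis genes and 5 splicing factors were called lower, and without sh-CHASERR replicate 1 they numbered 6 and 5. The lower ribosome biogenesis genes numbered 16 with equal totals and 14 with the length and GC correction. Under that correction the lower histone genes numbered 6. The lower splicing factors numbered 6 with median-ratio scaling and 5 with no filter on low values. Of 10 nuclear-retained and intron-rich RNAs, which can vary with RNA and library quality, 3 fell and none rose (4 lower and 1 higher adjusted over the list alone), with a median of -0.33 and a camera adjusted p = 0.0613 (adjusted p = 0.683 with an estimated correlation). Its median relative to the sh-NC mean was -0.43, -0.15 and -0.57 in sh-CHASERR replicates 1, 2 and 3. There was 1 lower gene in that list without sh-NC replicate 3, sh-CHASERR replicate 1 or sh-CHASERR replicate 3.

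Some genes of energy and lipid metabolism were higher. Of 22 glycolysis genes, 9 rose and none fell (10 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.29. The lactate exporter SLC16A3 rose from 53.9 ± 3.08 to 84.2 ± 5.06 FPKM (log2 fold change 0.64, limma adjusted p = 0.00238), and ENO2, PFKL and TPI1 rose with 0.69, 0.61 and 0.55 (TPI1 with 0.30 under quantile normalization). Of 36 nuclear genes of oxidative phosphorylation, 10 rose and none fell (11 higher adjusted over the list alone), with a median of 0.21. COX7A2, a subunit of cytochrome c oxidase, rose from 139 ± 12.7 to 209 ± 15.01 FPKM (log2 fold change 0.59), and ATP5MC1, of ATP synthase, rose with 0.49 but was not called with the length and GC correction (0.20). Camera called both lists higher (adjusted p = 4.22e-05 and 2.86e-07; adjusted p = 0.51 for each with an estimated correlation), but the call on oxidative phosphorylation was lost with quantile normalization (median 0.15). Without sh-NC replicate 1, 4 glycolysis and 3 oxidative phosphorylation genes were called higher, without sh-NC replicate 3 they numbered 4 and 5, without sh-CHASERR replicate 1 5 and 5, without sh-CHASERR replicate 2 5 and 10, and without sh-CHASERR replicate 3 6 and 4. They numbered 4 and 6 with equal totals, 4 and 4 with quantile normalization, 5 and 5 with the replicate block and 4 and 5 with no filter on low values. Of 24 cholesterol biosynthesis genes, 8 rose and none fell (9 higher adjusted over the list alone), with a median of 0.11 (0.23 without sh-NC replicate 3 and 0.003 with equal totals) and a camera adjusted p = 0.00256 (adjusted p = 0.51 with an estimated correlation). FDPS, farnesyl diphosphate synthase, rose from 46.2 ± 3.63 to 68.2 ± 8.04 FPKM (log2 fold change 0.55). The number of higher genes in that list was 2 without sh-NC replicate 1, 5 without sh-NC replicate 3, 3 without sh-CHASERR replicate 1, 5 without sh-CHASERR replicate 2 and 4 without sh-CHASERR replicate 3. It was 3 with equal totals, 4 with the replicate block and 5 with no filter on low values. Of 17 genes of fatty acid synthesis and lipid droplets, 3 rose and none fell (3 higher adjusted over the list alone), with a median of 0.13 (0.19 without sh-NC replicate 3 and 0.02 with equal totals) and a camera adjusted p = 0.00599 (adjusted p = 0.51 with an estimated correlation). The desaturases FADS2 and SCD rose with log2 fold changes of 1.09 and 0.73, and the third gene, named after its value was seen, was SREBF1, a transcription factor of lipid synthesis. Without sh-NC replicate 1 or sh-CHASERR replicate 3, 2 genes of that list were called higher. With the length and GC correction there were 5. Equal totals, which brought the medians of the cholesterol and fatty acid lists down, also lowered the median of all genes from -0.073 to -0.175. Camera compares a list with other genes.

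Cytosolic ribosomal protein genes had a slightly higher median in sh-CHASERR, but not under every scaling, and fry did not call the list (adjusted p = 0.0863). Other lists called by camera also lacked a fry call. They were the lists of antigen presentation (fry adjusted p = 0.0636), unfolded protein response and ATF4 (0.0863), splicing factors (0.0863) and histones (0.0889). The same held for cholesterol (fry adjusted p = 0.0636), fatty acid (0.133), extracellular matrix (0.251), heat shock (0.337) and astrocyte lists (0.133). Of 61 ribosomal protein genes tested, 7 rose and none fell by limma, and 0 were called adjusted over the list alone. At an unadjusted p under 0.05, 22 were higher and 0 lower, and the authors' deposited table calls 2 higher and 0 lower. The median log2 fold change was 0.22, with a camera adjusted p = 8.55e-09 (adjusted p = 0.51 with an estimated correlation), and it turned to -0.03 with quantile normalization. RPS19 rose from 125 ± 17.9 to 176 ± 12.8 FPKM (log2 fold change 0.50, limma adjusted p = 0.0163). The higher members numbered 1 without sh-NC replicate 1, 1 without sh-NC replicate 3, 3 without sh-CHASERR replicate 1 and 0 without sh-CHASERR replicate 3. They also fell to 2 with equal totals, 3 with median-ratio scaling, 1 with quantile normalization, 3 with the replicate block and 0 with no filter on low values. RPS19 lost its call without sh-CHASERR replicate 3 (log2 fold change 0.44), with quantile normalization and with no filter on low values. Ribosomal protein genes have many processed pseudogenes, so their values are uncertain where shared reads were split. Fold change fell with transcript length across genes (Spearman rho -0.21), from a median of 0.13 in the shortest of 10 length classes to -0.15 in the longest, and rose with GC content (rho 0.29). Of single libraries, sh-NC replicate 3 deviated the most with GC content from the mean over both groups (rho -0.69), followed by sh-CHASERR replicate 3 (rho 0.47). Such a deviation includes the difference between the groups.

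**Figure D2:**
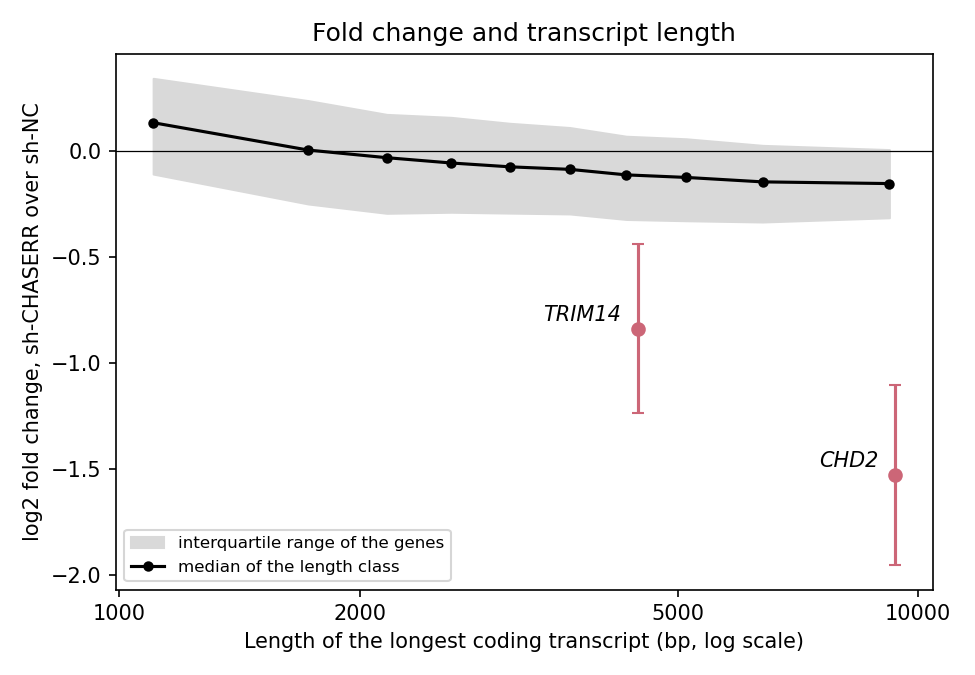
Median log2 fold change (sh-CHASERR over sh-NC, vertical axis) of 10 classes of genes by length of the longest coding transcript (bp, log axis), with the interquartile range of the genes in grey and CHD2 and TRIM14 in red with 95% confidence intervals. The class medians go from 0.13 to -0.15, and CHD2 lies at -1.53.

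Some extracellular matrix and collagen genes were higher. Of 27 tested, 6 rose and 1 fell (6 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.27 (0.16 without sh-NC replicate 1) and a camera adjusted p = 0.000542 (adjusted p = 0.683 with an estimated correlation). COL1A2, a chain of type I collagen, rose from 98.7 ± 19.9 to 155 ± 19.2 FPKM (log2 fold change 0.66, limma adjusted p = 0.0104), while THBS1, an adhesive glycoprotein, fell from 70.3 ± 8.34 to 45.0 ± 7.32 FPKM (log2 fold change -0.64). The higher members numbered 2 without sh-NC replicate 1, 2 without sh-NC replicate 2, 9 without sh-NC replicate 3, 1 without sh-CHASERR replicate 1, 4 without sh-CHASERR replicate 2 and 3 without sh-CHASERR replicate 3. They were 1 with equal totals, 1 with the replicate block, 3 with no filter on low values, 10 with quantile normalization and 14 with the length and GC correction, and COL1A2 lost its call with no filter. Of 18 heat shock and chaperone genes, 4 rose and none fell (4 higher adjusted over the list alone), with a median of 0.10 (0.17 without sh-NC replicate 1, 0.03 without sh-CHASERR replicate 1 and 0.28 without sh-CHASERR replicate 3) and a camera adjusted p = 0.00998 (adjusted p = 0.706 with an estimated correlation), and the call was lost with quantile normalization. HSPB1, a small heat shock protein like CRYAB, rose from 798 ± 94.6 to 1240 ± 56.9 FPKM (log2 fold change 0.64; 0.35 and not called with the length and GC correction), and HSPA8 and AHSA1, named after their values were seen, rose too. There were 2 higher heat shock genes without sh-NC replicate 1, without sh-CHASERR replicate 1 or without sh-CHASERR replicate 2, and also with equal totals, with quantile normalization and with no filter. Of 9 astrocyte markers, GFAP and S100B rose and none fell (2 higher adjusted over the list alone), with a median of 0.27 (0.18 without sh-CHASERR replicate 1) and a camera adjusted p = 0.0473 (adjusted p = 0.51 with an estimated correlation). That list lost its call without sh-NC replicate 2 (median 0.29), sh-NC replicate 3 (median 0.06) or sh-CHASERR replicate 2 (median 0.24), with median-ratio or upper-quartile scaling, with quantile normalization and with the length and GC correction. S100B (log2 fold change 0.52) lost its call without any 1 library except sh-CHASERR replicate 1 (0.38 to 0.58). It was also not called with equal totals, the replicate block, the length and GC correction or no filter on low values.

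**Figure D3:**
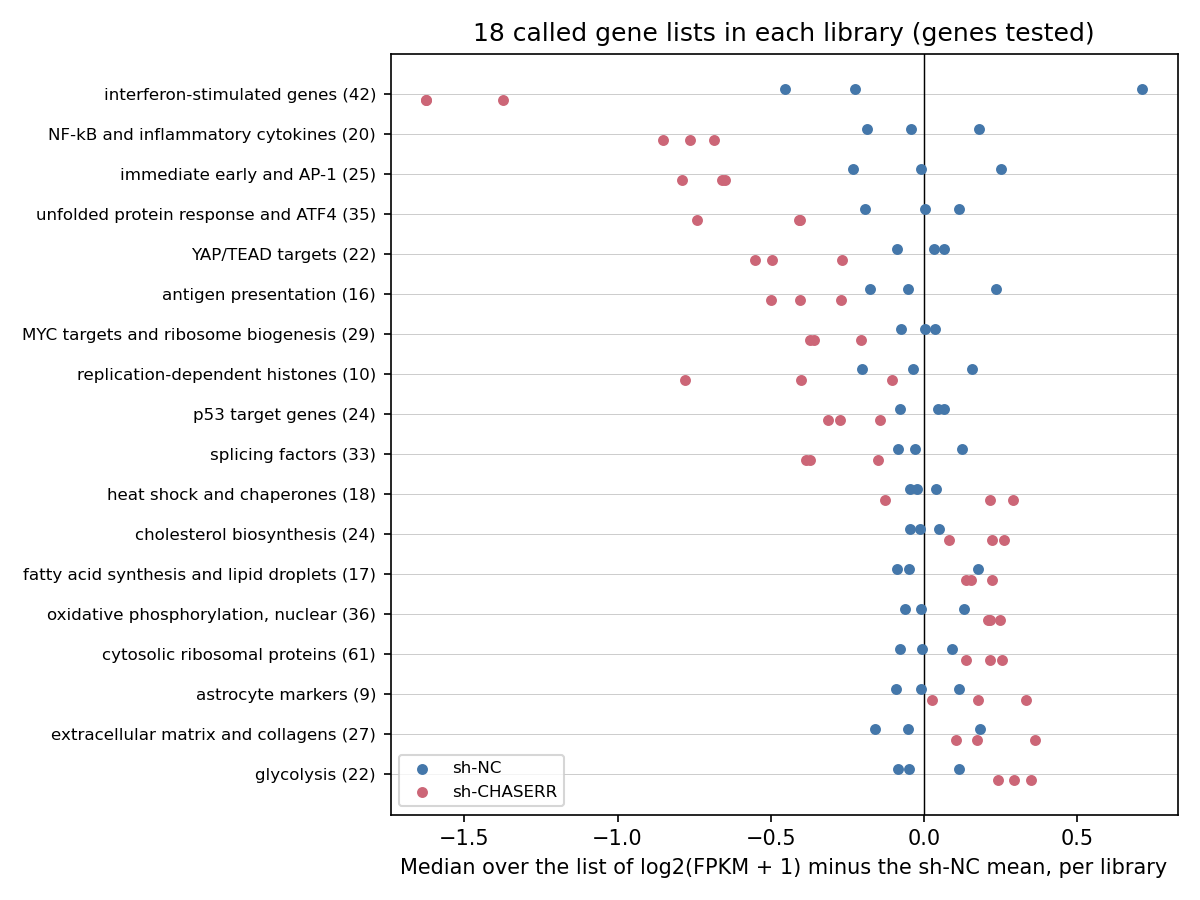
Median over each called gene list of log2(FPKM + 1) minus the sh-NC mean (horizontal axis), for each of 3 sh-NC libraries (blue) and 3 sh-CHASERR libraries (red), with the number of genes tested after each name. The interferon-stimulated genes have the lowest values in sh-CHASERR (-1.62, -1.37 and -1.62), and the ribosomal protein list, with a median log2 fold change of 0.22, turned to -0.03 under quantile normalization.

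Lists without a call included those of the cell cycle. Of 35 genes of mitosis and G2/M, 1 was higher and none lower (0 adjusted over the list alone), with a median log2 fold change of 0.05, and of 35 genes of DNA replication and S phase, limma called 0 either way, with 2 higher and 1 lower at an unadjusted p under 0.05 and 0 called in the authors' deposited table. Their camera adjusted p were 0.0841 and 0.139 (adjusted p = 0.742 and 0.74 with an estimated correlation). The higher mitosis gene, KIF20A (log2 fold change 0.40), kept its call without sh-NC replicate 3 and lost it without any other 1 library (0.36 to 0.42). It was also not called with equal totals or with the replicate block. Of 24 chromatin remodelling genes of the CHD and related families, CHD2, INO80 and, named after their values were seen, CHD1 and CHD9 fell and none rose (4 lower adjusted over the list alone), with a median of -0.17 and a camera adjusted p = 0.281 (adjusted p = 0.824 with an estimated correlation). Of 11 tested genes near CHASERR in 15q26, CHD2 and, named after its value was seen, ARRDC4 fell and RGMA rose (2 lower and 2 higher adjusted over the list alone), with a median of -0.18 and a camera adjusted p = 0.606 (adjusted p = 0.848 with an estimated correlation). RGMA, a guidance molecule, rose from 4.77 ± 0.424 to 8.08 ± 1.34 FPKM (log2 fold change 0.65) and lost its call without sh-NC replicate 1 (0.58), and without sh-CHASERR replicate 3 only 1 gene of the region was called lower. Markers of other cell types were few: 2 oligodendrocyte, 3 myeloid, 4 endothelial, 4 epithelial and 4 fibroblast and pericyte markers reached the filter. These lists were too small for a test. Of their genes, named after the values were seen, CD14, KDR, ESAM and KRT7 fell and ACTA2 and THY1 rose. Of 15 genes used for normalizing, ACTB, PGK1 and, named after their values were seen, GAPDH rose, TBP fell and 11 were not called (3 higher and 1 lower adjusted over the list alone), with a median of 0.11 and a camera adjusted p = 0.175 (adjusted p = 0.543 with an estimated correlation). The higher genes of this list numbered 0 without sh-NC replicate 1 or 3, 1 without sh-CHASERR replicate 1 or 3 and 2 without sh-CHASERR replicate 2, and 0 were lower when any 1 library was left out. ACTB lost its call without sh-NC replicate 1 (0.41) or 3 (0.49) or sh-CHASERR replicate 1 (0.52) or 3 (0.40), and PGK1 without sh-NC replicate 1 (0.38) or 3 (0.44) or sh-CHASERR replicate 2 (0.40). ACTB and PGK1 had log2 fold changes of 0.48 and 0.46 as deposited, 0.35 and 0.33 with equal totals, 0.58 and 0.56 with median-ratio scaling, 0.53 and 0.51 with upper-quartile scaling, and 0.04 and 0.27 with quantile normalization. PGK1 was not called with equal totals, ACTB was not called with the replicate block, and neither gene was called with quantile normalization or with no filter on low values.

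The authors' deposited table holds its own comparison of the groups. In it, 1965 of 16883 genes with a p-value had an adjusted p under 0.05, with 800 higher and 1165 lower in sh-CHASERR. Of 11016 genes with values in both comparisons, 1478 were called in both, each in the same direction, 786 by limma on FPKM alone and 245 in the authors' deposited table alone. The log2 fold changes had a Spearman rho of 0.96 across these genes. For CHD2 the authors' deposited table gives a fold of 0.345, with means of 3744 and 1291 normalized counts and an adjusted p of 1.9e-14, and for TRIM14 a fold of 0.488 and an adjusted p of 0.0208.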

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

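The scalings, the stricter filter, the correction for length and GC content and limma's treat were chosen after seeing the data. Because the table holds FPKM, the planned runs of DESeq2, limma-voom, edgeR with relative log expression, library-size or upper-quartile factors, the 5 CPM filter and glmTreat were not run. CHD2 stayed lower and called under every alternative run, from -1.74 with a pseudocount of 0.1 to -1.31 without sh-CHASERR replicate 3; leaving out 1 library gave -1.73 at the lowest (without sh-CHASERR replicate 2). Leaving out 1 library gave 1058 to 2205 changed genes, 261 to 705 higher, 797 to 1646 lower and 203 to 304 changed at least 2-fold, with 18 to 20 lists called. With a pseudocount of 0.1, 596 genes changed at least 2-fold, since low genes then move further on the log scale, and with no filter 487 were higher. No label says that the replicate numbers pair the libraries. Deviations of same-numbered libraries from their group means correlated at 0.38, -0.34 and -0.34. With 3 libraries per group the deviations depend on each other, so these values cannot settle whether the libraries are paired. With the replicate block 1497 genes changed, 426 of them higher. Equal totals gave 408 higher genes, quantile normalization 1269, and the length and GC correction 1309; the cause was not tested. Quantile normalization reversed the ribosomal protein list (median -0.034). At 5 FPKM or more, with fewer genes tested (6338), 1415 genes changed, 774 of them lower and 153 at least 2-fold. Against a minimum fold of 1.2, treat called 458 genes, 77 higher and 381 lower. Camera with an estimated correlation called 0 lists (2 at an unadjusted p under 0.05) and fry called 9. Over all alternatives, values of named genes had the same direction, with 1387 of the same call and 159 no longer called, and medians of called lists had 283 of the same call and 39 no longer called.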

Other observations

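The tests of a response to the hairpin or its delivery, of the 15q26 region, and those that use scalings, matched random lists or a correction for length and GC content were chosen only after the results were seen, as were the division of the stress list, the terms picked out here and the genes VEGFA, SLC2A1, SLC7A11, ABCC2, TALDO1, TKT, FTL, GSTP1 and GSTM3.

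Single genes of the Notch, apoptosis and hypoxia lists were lower too, but camera called none of these lists. Of all 11059 genes tested, 1481 were lower. Of 12 tested Notch pathway genes, HEY1, NRARP and, named after their values were seen, JAG1 and DLL1 fell and none rose (4 lower adjusted over the list alone; log2 fold change -1.60 for HEY1 and -1.30 for NRARP, which was not called with no filter on low values), without a call on the list (camera adjusted p = 0.211; adjusted p = 0.723 with an estimated correlation). Without sh-NC replicate 1, 2 of them were called. Of 25 apoptosis regulators, 6 fell and none rose (7 lower adjusted over the list alone), among them PMAIP1 (-1.44), a BH3-only protein, and the death receptor TNFRSF10B (-0.73), with no call on the list by camera (adjusted p = 0.0801; adjusted p = 0.576 with an estimated correlation) but a call by fry (adjusted p = 0.0321). The number was 4 without sh-CHASERR replicate 1. Hypoxia genes went both ways, since CA9 and SLC2A1 rose while ADM (-1.96), DDIT4 (-1.44) and VEGFA fell, of 22 tested (3 higher and 3 lower adjusted over the list alone; median 0.11, mean -0.001; camera adjusted p = 0.198). The higher genes numbered 0 without sh-NC replicate 1, 1 without sh-CHASERR replicate 1 or 2 and 5 without sh-CHASERR replicate 3, and the lower ones 1 without sh-NC replicate 2. DDIT4 lost its call without sh-NC replicate 2 (-1.37) or with no filter on low values, and went to -0.95 without sh-CHASERR replicate 3.

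The oxidative stress list divided as well. Of 22 tested genes, HMOX1, which degrades heme, fell from 93.1 ± 20.8 to 21.4 ± 4.96 FPKM (log2 fold change -2.07, limma adjusted p = 0.000128), and OSGIN1, SLC7A11 and ABCC2 fell too, while TALDO1 and TKT, of the pentose phosphate pathway, and FTL were among those that rose (4 higher and 5 lower adjusted over the list alone). Its median was 0.07 and its mean -0.14, and camera made no call (adjusted p = 0.469; adjusted p = 0.8 with an estimated correlation). The higher genes of this list numbered 0 without sh-NC replicate 1, 1 without sh-NC replicate 3, 1 without sh-CHASERR replicate 1 and 2 without sh-CHASERR replicate 3. In the enrichment tests, pentose phosphate genes were over-represented among higher genes (7 of 22, Fisher's exact test adjusted p = 0.0251), as were complex I (14 of 39, adjusted p = 9.11e-05) and the pathway of xenobiotic metabolism by cytochrome P450 (9 of 19, adjusted p = 0.000365), whose higher genes were mostly glutathione transferases such as GSTP1 and GSTM3. Among lower genes, ribosome biogenesis in eukaryotes (21 of 70, adjusted p = 0.00122) and tRNA binding (18 of 52, adjusted p = 0.0166) were over-represented. Fisher's exact test treats genes as independent, so these adjusted p are too small where genes vary together. The enrichment tests were run only on the calls from all libraries. Without sh-NC replicate 1, higher calls went from 790 to 261 and lower calls from 1481 to 797. In the unfolded protein response and ATF4 list, 15 of 21 genes of the ATF4 branch and amino acid metabolism fell and none rose (median -0.88). Of the other 14 genes, mostly of folding and degradation in the endoplasmic reticulum, 3 rose and 2 fell (median 0.08). XBP1, a transcription factor named after its value was seen, was 1 of the 2 that fell.

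The fall of interferon-stimulated genes stands out in size. Over the length and GC correction and 4 other scalings, the list median came no closer to 0 than -1.383, which argues against those trends as the whole cause, and 33 of 42 members were still called lower without sh-NC replicate 3, the library with the highest values. An interferon response to the control hairpin or its delivery stays open, because no untransfected libraries were analysed here. Without such libraries, this explanation and a lowered response in sh-CHASERR cannot be told apart. The sh-NC libraries themselves spanned 1.17 in the list median (log2), a spread that does not decide between them. The same limit holds for TRIM14, a member of this list. It also holds for the other lists that were lower in sh-CHASERR, among them the NF-kB, immediate early, ATF4 and p53 lists. Whether those genes responded to the control hairpin or its delivery was not tested.

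CHD2 fell although loss of CHASERR is known to raise CHD2 in other systems. A trend with transcript length or GC content does not account for it, since the upper limit after correction was -1.07 (log2 fold change -1.34, SE 0.12) and 0% of the 200 genes closest in length fell as far. Nor did the region fall as a whole, as the other tested genes of 15q26 had a median of -0.15. What stays open and untested is whether the hairpin also acts on transcripts that run from CHASERR into CHD2. Whether CHASERR itself fell, and whether RNA or library quality had a part in the fall of CHD2, also stay open. The labels name no further hairpin against CHASERR. For CHD2 and for every list, effects of this hairpin on other RNAs therefore cannot be told apart from effects of targeting CHASERR.

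The rises of housekeeping lists may be partly technical. The ribosomal protein median lay at percentile 64.13 of random lists matched on length and abundance and went to -0.034 under 1 scaling, so either a trend with length and abundance or the scaling could produce it. The oxidative phosphorylation median lay at percentile 83.77 of its matched lists, consistent with the same trend, though it stayed at 0.078 or more under the 4 scalings. The glycolysis median lay at percentile 99.99 and stayed at 0.16 or more, which argues against both as the whole cause. The random lists were not matched on GC content, so they do not test a trend with it. Their genes were drawn singly, so a percentile may be too extreme for genes that vary together. What raised the glycolysis genes stays open.

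For the count of changed genes, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 2271 genes, as large a count came from 1 of the 10 splits, the real one, and the highest of the others was 0. Every other split mixes sh-NC and sh-CHASERR libraries on each side. The difference between the groups then widens the spread within a side and lowers the count. The 0 therefore does not show how many calls chance alone would give.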
